A study of Oryza sativa with 11 samples.

How the data were processed

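RNA from laser-microdissected flower bases of rice was amplified and labelled with Cy3 or Cy5, and each of 11 arrays held 2 such RNAs, per the labels' protocols. Arrays were read with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes. The deposited scanner files give the mean spot intensity and the median local background intensity of each channel. They also give a log10 ratio of red over green, per the file headers, which the authors' software had corrected for background and dye. Further columns are 0 or 1 flags for signal above background, saturation and outlying spots, per the file headers. The series value table holds the authors' log10 ratios. It equals the log10 ratio of the scanner files on 10 arrays and has the opposite sign on array 7, all column medians are 0, and the direction it was meant to have is not stated.

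Groups and dyes were taken from the labels. The NIL(qSH1) abscission layer was in Cy5 on arrays 1 to 6 and in Cy3 on arrays 7 to 11, and every log2 ratio was turned to that layer over the other RNA. Array 1 is the only array whose labels list Cy5 as the first channel, and the value table does not turn it. The slides held arrays 1, 7, 8 and 9, arrays 2 and 3, arrays 4, 5 and 6, and arrays 10 and 11. Only the first of these slides held both young and older panicles, with array 1 as its young array. Slide and stage therefore largely go together on arrays 1 to 7, while each slide with region arrays held an upper and a lower one. Saturated spots numbered 0, and 9 to 46 spots per array were flagged as outliers and given no weight. In the channel of the other RNA 25.7% to 58.5% of probes were well above background. The number of arrays limits the precision.

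In R 4.3.3 with limma 3.58.1, background was corrected by normexp with an offset of 50 and ratios were normalized within arrays by loess, with control spots left out. Of 42429 probes, 30183 that were well above background in either channel on at least 2 arrays were tested, covering 20539 genes. A linear model with 4 coefficients (variety difference in young and in older panicles, upper region, lower region) was fitted to all 11 arrays with 7 residual degrees of freedom and a prior of 2.50, so that comparisons with 2 arrays borrow the spread of the others. Moderated tests were 2-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. The variety difference is the mean over 7 arrays, and the stage difference is older minus young. For 31 gene lists fixed beforehand, medians, counts and limma's camera with a preset correlation of 0.01 were computed, and 0 lists passed in any comparison with an estimated correlation, in either direction of array 1.

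Groups, designs, gene lists, the naming rule and most alternatives were fixed before the data were examined. The rule names every measured shattering gene and, per comparison, up to 10 genes higher and 10 lower with the largest ratio among those past the threshold, of 1 direction on all arrays and with a description that is not hypothetical, unknown or expressed protein. Blank descriptions and those without a hit were also left out. Where none passed, the 5 per direction with the smallest p were named as not passing, and per gene list up to 4 members past the threshold. A gene is represented by its brightest probe. Where a gene was not well above background in 1 RNA on every array of a comparison, a bound ("at least") is given from per-channel signals after loess and Aquantile normalization, which is open to dye bias. Of 29689 locus IDs and 40850 accessions, 0 matched the reference table, so names are those of the files.

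Alternatives were the log10 ratio and value table of the authors, median centring without loess, an offset of 10, scaling between arrays, no filter, a filter asking for both channels on 8 arrays, flagged spots kept, a dye term, 1 variety coefficient, arrays 1 and 2 averaged, random blocks for alike labels and for slides, array weights, an intensity trend with a robust prior, 1 probe per gene, only the arrays compared, pairing by stage and leaving out each array. Turning array 1, turning and averaging it with array 2, turning arrays 2 and 3, giving the stages on their own and, for heat shock genes, a fit without arrays 1 and 7 were added after seeing the data. On simulated data of 30183 probes with 100 changed per size, the variety comparison recovered 94% of log2 changes of 1 and 100% of those of 2 with 9 false calls. The upper comparison recovered 70% and 91% with 7 false calls, and the comparison with both flanking regions 83% and 99% with 9. The simulated noise was drawn independently for each probe and array, with the same spread of a probe on all arrays. Dim arrays and an array that runs against the others were not simulated, so these shares do not measure recovery in the real data.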

Results

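The series measured transcripts in the abscission layer at the base of the rice flower, the narrow band of cells along which a ripe grain detaches. Cells were cut out by laser microdissection from NIL(qSH1), a near-isogenic line named for the seed shattering locus qSH1 that sheds its grain easily, and from Nipponbare, which does not shed it easily. Each of 11 Agilent arrays compared 2 RNAs in 2 colours, Cy3 and Cy5. Arrays 1 to 7 set the NIL(qSH1) abscission layer against that of Nipponbare, 3 of them from young panicles of 7 to 10 mm and 4 from older panicles of 35 to 140 mm. Panicle lengths of NIL(qSH1) and Nipponbare were unequal on arrays 3 (10 and 7 mm) and 4 (35 and 38 mm). They were also unequal on arrays 5 (140 and 135 mm) and 6 (102 and 115 mm). Variety and panicle length cannot be told apart on those arrays. Arrays 4, 5 and 6 shared 1 slide. Arrays 8 and 10 set the NIL(qSH1) layer against the region just above it, and arrays 9 and 11 against the region just below it, all from older panicles. Panicles were 50 to 100 mm long for arrays 8 and 9, and 140 mm with flowers of 7 to 8 mm for arrays 10 and 11. Every ratio below is NIL(qSH1) abscission layer over the other RNA on the log2 scale. The share of probes well above background in the abscission layer channel was 57.8% to 66.9% on arrays 1 to 6, 14.0% to 14.7% on arrays 7 to 9, and 41.0% and 41.8% on arrays 10 and 11. Array 1 ran against arrays 2 and 3, with a correlation across probes of -0.75 and -0.43, although the labels give all 3 the same dyes, while arrays 2 and 3 correlated at 0.51. Probes are not independent replicates, and the direction of array 1 is therefore not settled, so values are given with its dyes as labelled and with its sign turned. The labels do not tie arrays to plants, so p-values measure only the spread between arrays, which may be technical. Both RNAs of arrays 1 and 2, the layer RNA of arrays 7, 8 and 9, and that of arrays 10 and 11 carry alike labels and could be shared. With an intensity trend and a robust prior limma called 0 probes in each of the 6 comparisons, and the counts below are without them.

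The first comparison asked how the abscission layer of the shattering line differs from that of Nipponbare. At the qSH1 locus (Os01g0848400, a homeobox gene) the ratio over 7 arrays was 1.11 (SE 0.25, adjusted p = 0.314, above 0 in 6 of 7 arrays). In the 4 older arrays it was 1.74 (SE 0.34, adjusted p = 0.115, above 0 in 4 of 4), with 2.37, 1.89 and 2.55 on arrays 4, 5 and 6 and 0.16 on array 7. The 3 probes of the locus differed in size, with means over arrays 4 to 6 of 2.27, 0.61 and 1.87, and the first, the brightest, is the one given throughout. On young arrays 1, 2 and 3 the second probe gave 0.30, -0.58 and -0.80 and the third 0.03, 0.19 and -0.01, with 0.11 and -0.06 on array 7. The 3 young arrays gave -0.30, 0.65 and 0.42, a mean of 0.26 (SE 0.39). OSH15 (Os07g0129700), a KNOX-class homeobox gene of shoot development, had ratios of 0.80 over all 7 arrays (SE 0.14, adjusted p = 0.232) and 1.28 in the older arrays (SE 0.18, adjusted p = 0.0661, above 0 in 4 of 4). Of the 8 measured shattering genes, a list fixed by locus, 0 passed over all genes tested and 4 were higher when adjusted over the list alone: OSH15, the qSH1 locus, Os04g0649100 (a conserved hypothetical protein, 0.50, SE 0.13) and Os05g0455200 (homeodomain protein JUBEL2, 0.35, SE 0.10). In the older arrays 6 of the 8 were higher on that scale, with a list median of 0.66. By camera the shift of the list had an adjusted p of 0.000236 over 7 arrays and 5.83e-06 in the older arrays, but adjusted p = 0.185 and adjusted p = 0.0739 with an estimated correlation. Median centring without loess moved the list median from 0.45 to 1.58 over 7 arrays and to 2.08 in the older arrays, and both camera calls were then lost. Photosynthesis genes, a marker of green tissue, had a median of 0.40 in the same older arrays, with 0.06, 0.40, 0.75 and 0.01 on arrays 4 to 7, and 0 of 55 passed over the list alone. That median was 1.04 with the log ratios of Feature Extraction, the scanner software, and 0.86 under median centring. Their camera adjusted p of 0.00222 became adjusted p = 0.910 with an estimated correlation.

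**Figure D1:**
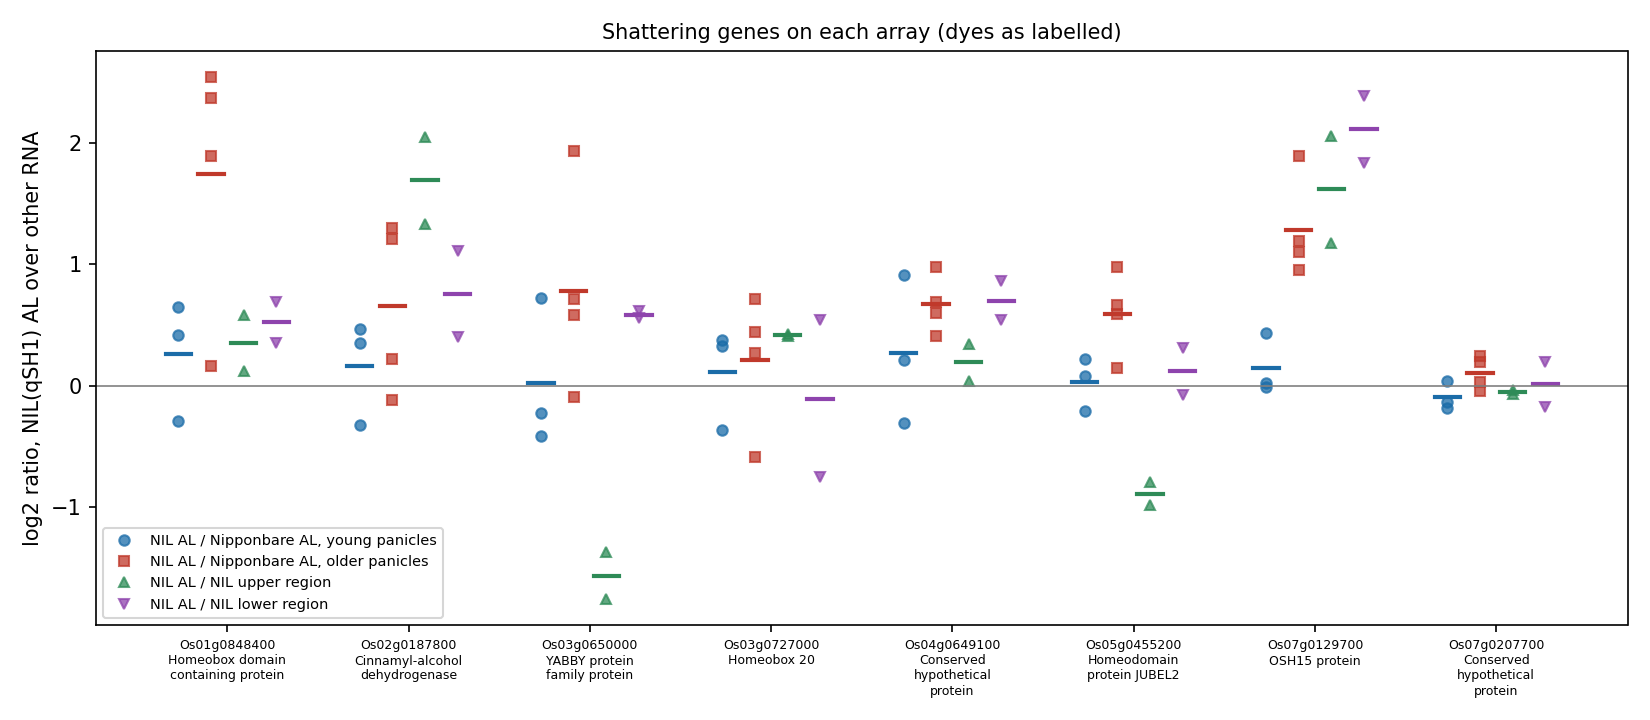
Log2 ratios of the 8 measured shattering genes, NIL(qSH1) abscission layer (AL) over the other RNA, with dyes as labelled. Points are single arrays and bars are group means over 3 young arrays, 4 older arrays and 2 arrays each for the upper and lower regions; the qSH1 locus reached 2.55 on array 6 and OSH15 lay above 0 on all 4 region arrays.

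Over all 7 arrays limma called 1 probe of 30183 higher and 0 lower, with 3799 at an unadjusted p under 0.05. The gene was Os05g0178300, a non-protein-coding transcript, with a ratio of 0.77 (SE 0.06, adjusted p = 0.00619, above 0 in 7 of 7). Turning array 1 gave 0.73 (adjusted p = 0.00810, above 0 in 6 of 7). A second probe of that gene had 0.68 and did not pass as labelled (adjusted p = 0.0547, above 0 in 6 of 7), and the Nipponbare signal was well above background on 3 of 7 arrays. In the older arrays 15 probes of 8 genes were higher and 0 lower, with 3847 at an unadjusted p under 0.05. Os03g0184300, a family 8 glycosyl transferase, rose by 2.14 (SE 0.27, adjusted p = 0.0458), and Os02g0726300, a Dof zinc finger gene, by 1.75 (SE 0.20, adjusted p = 0.0228). Os02g0757700, an F-box gene, rose by 1.57 (SE 0.13, adjusted p = 0.00488), Os05g0178300 by 1.20 (SE 0.08, adjusted p = 0.00128) and the protein kinase gene Os05g0481100 by 1.16 (SE 0.15, adjusted p = 0.0495), each above 0 in 4 of 4 arrays. In the young arrays 0 probes were called in either direction by limma, with 1627 at an unadjusted p under 0.05. Leaving out array 4 ended the 1 call over 7 arrays, while the count was 445 without array 1, 3 without array 7 and 2 without array 8 or array 10. It was 19 with the log ratios of Feature Extraction, 7 with a background offset of 10, 5 with arrays scaled to each other, 46 with a gene-specific dye term and 15902 (14375 higher, 1527 lower) under median centring. The probe called over 7 arrays was not among the calls with those log ratios or with arrays scaled to each other. Nor was it the 1 probe called with a stricter filter on dim probes, or that called with only the 7 arrays compared. The dye term rests on array 7 against arrays 4 to 6, the only arrays of 1 kind with both dye orders.

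Ribosomal protein genes had a median ratio of -0.25 in the older arrays, where 74 of 281 were lower when adjusted over the list alone and 0 over all genes tested. Examples, chosen after their values were seen, are the 60S protein L26B gene Os01g0140500 at -1.08 (SE 0.16) and the 40S protein S21 gene Os03g0345200 at -0.70 (SE 0.12). The camera call for this list, adjusted p = 8.41e-27, was lost with an estimated correlation (adjusted p = 0.882), and the median turned to 0.86 when arrays were only centred on their medians, a scaling that moved the median of all probes over 7 arrays from 0.02 to 0.39. With the log ratios of Feature Extraction it was -0.54. Over 7 arrays its median was -0.13, 0.83 under that centring or -0.31 with those log ratios, with 15 lower over the list alone, adjusted p = 1.41e-18 by camera and adjusted p = 0.512 with an estimated correlation. That list is named for cytosolic ribosomes, and 45 of its 281 members are described as 50S, 30S or chloroplast proteins, which belong to organelle ribosomes. Among 24 expansins, proteins that loosen the cell wall, Os03g0822000 (OsEXPA7) had a ratio of 1.55 (SE 0.22) in the older arrays and Os10g0556100 (EXPB4) -1.12 (SE 0.21), and 1 was higher and 2 lower over the list alone. Both were named after their values were seen, and 1 of the 3 other probes of the first gene (-0.03 over 7 arrays) and all 5 others of the second (-0.41 to -0.25, against -0.75) showed smaller ratios. Against the upper region both genes were lower in the layer over the list alone. Over all genes tested neither passed there by limma (adjusted p = 0.0691 and adjusted p = 0.133). OsEXPA7 thus had opposite directions in these 2 comparisons. Jasmonate genes had a median of -0.20 and a mean of -0.26 over 7 arrays, with a camera adjusted p of 0.00912 and adjusted p = 0.630 with an estimated correlation, and array 3 alone stood at -1.24. Under median centring the jasmonate median was 0.46.

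With array 1 turned, an alternative chosen after the data were seen, the variety comparison called 612 probes higher and 380 lower. Arrays 1 and 2 could share their RNAs, and averaging them after this turn, also chosen after the data were seen, left 12 higher and 3 lower. Among those calls were 1 of 48 histone genes, 2 of 137 cell cycle genes and 0 of 162 heat shock genes. Turning arrays 2 and 3 in place of array 1, likewise chosen later, gave 23 higher and 29 lower. With averaging the qSH1 locus (adjusted p = 0.0795), OSH15 (Os07g0129700, adjusted p = 0.0586) and Os04g0649100 (adjusted p = 0.0574) did not pass. Without averaging, as in the values that follow, the qSH1 locus (Os01g0848400) passed by its brightest probe at 1.19 (SE 0.24, adjusted p = 0.0365, above 0 in 7 of 7). Its other probes did not, at 0.04 (adjusted p = 0.842) and 0.81 (adjusted p = 0.0660), each above 0 in 4 of 7, and the second lay below 0 on all 3 young arrays. OSH15 passed at 0.79 (SE 0.14, adjusted p = 0.0245) and Os04g0649100 at 0.59 (SE 0.10, adjusted p = 0.0219), though the second probe of Os04g0649100 did not, at 0.48 (adjusted p = 0.0755). The largest described increases were Os03g0184300 at 1.56, the serpin gene Os03g0610800 at 1.52, the auxin response repressor gene Os03g0742900 (AUX/IAA family) at 1.48 and Os02g0202000, a dehydration-responsive element binding protein, at 1.25. With averaging Os03g0184300 passed (adjusted p = 0.0488), and Os03g0610800 (adjusted p = 0.0718), Os03g0742900 (adjusted p = 0.0539) and Os02g0202000 (adjusted p = 0.0746) did not. Of 48 histone genes 12 were higher and 0 lower over all genes tested, with 19 higher and 1 lower over the list alone, and of 137 cell cycle genes 17 were higher and 0 lower, with 35 and 3 over the list alone. The histone H3 gene Os04g0450800 stood at 0.78 (SE 0.09) and the kinesin gene Os03g0114000 at 0.56 (SE 0.06). Both lists lost their camera calls at adjusted p = 0.162 with an estimated correlation. Of 162 heat shock genes, a marker of handling, 15 were higher and 1 lower, with 21 and 3 over the list alone and adjusted p = 0.251 with an estimated correlation. In the young arrays 975 probes were then higher and 664 lower, with 17 histone genes higher and 2 lower, 32 cell cycle genes higher and 0 lower, and 21 heat shock genes higher and 0 lower. These 3 lists had adjusted p = 0.0894, adjusted p = 0.127 and adjusted p = 0.184 with an estimated correlation. With averaging the young arrays gave 367 higher and 156 lower, with 9 histone, 25 cell cycle and 13 heat shock genes higher and 0 lower. Turning arrays 2 and 3 in place of array 1 turned the young directions, with 664 probes higher and 975 lower, and 17 histone, 32 cell cycle and 21 heat shock genes lower. The older arrays gave 60 higher and 25 lower.

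The labels' panicle lengths also allow the variety difference to be compared between stages. With dyes as labelled limma called 0 probes, with 1890 at an unadjusted p under 0.05 and a smallest adjusted p of 0.214. The smallest p belonged to Os05g0178300, whose Nipponbare signal was not well above background on any young array so that no size is given, and to Os02g0757700, whose older minus young difference was 1.55 (SE 0.19). The difference at the qSH1 locus was 1.49 (SE 0.52, adjusted p = 0.748) and at OSH15 1.14 (SE 0.28, adjusted p = 0.748). Photosynthesis genes had a median difference of 0.43, with 0 of 55 passing over the list alone, a camera adjusted p of 0.00168 and adjusted p = 0.942 with an estimated correlation. It was 1.14 with the log ratios of Feature Extraction, 0.77 with an offset of 10 and 0.96 under median centring. With array 1 turned 127 probes were higher and 200 lower in the older stage, and without array 1 the count was 310 (95 higher, 215 lower). Averaging the turned array 1 with array 2 left 21 higher and 67 lower. Turning arrays 2 and 3 in its place turned the balance, with 791 higher and 511 lower. With dyes as labelled the count was 2 without array 7 or with a gene-specific dye term, and 1 without array 8, without array 10 or with only the 7 arrays of this comparison. The fit with a dye term and that without array 7 are not separate here. The dye term rests on array 7 alone and takes up its value. Phenylalanine ammonia-lyase Os02g0626400, which opens the phenylpropanoid pathway, differed by 2.88 with array 1 turned (SE 0.45, adjusted p = 0.0277), with 2.69 and 0.87 at its other probes, and S-adenosylmethionine synthetase Os01g0323600 by 2.89 (SE 0.48, adjusted p = 0.0312). Heat shock protein 70 gene Os03g0276500 fell by 3.22 (SE 0.36, adjusted p = 0.0131), and at its other probes fell by 2.71 and fell by 2.16. With averaging Os03g0276500 passed (adjusted p = 0.0445), while Os02g0626400 (adjusted p = 0.0733) and Os01g0323600 (adjusted p = 0.0958) did not. With array 1 turned and not averaged, histone genes were lower in the older stage for 9 of 48 and higher for 1, with 22 lower and 3 higher over the list alone, a median of -0.53 and adjusted p = 0.108 with an estimated correlation. Heat shock genes were lower for 10 of 162 and higher for 1. Averaging left 3 histone and 7 heat shock genes lower and 0 higher. With arrays 2 and 3 turned instead there were 16 histone and 16 heat shock genes higher and 0 lower.

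**Figure D2:**
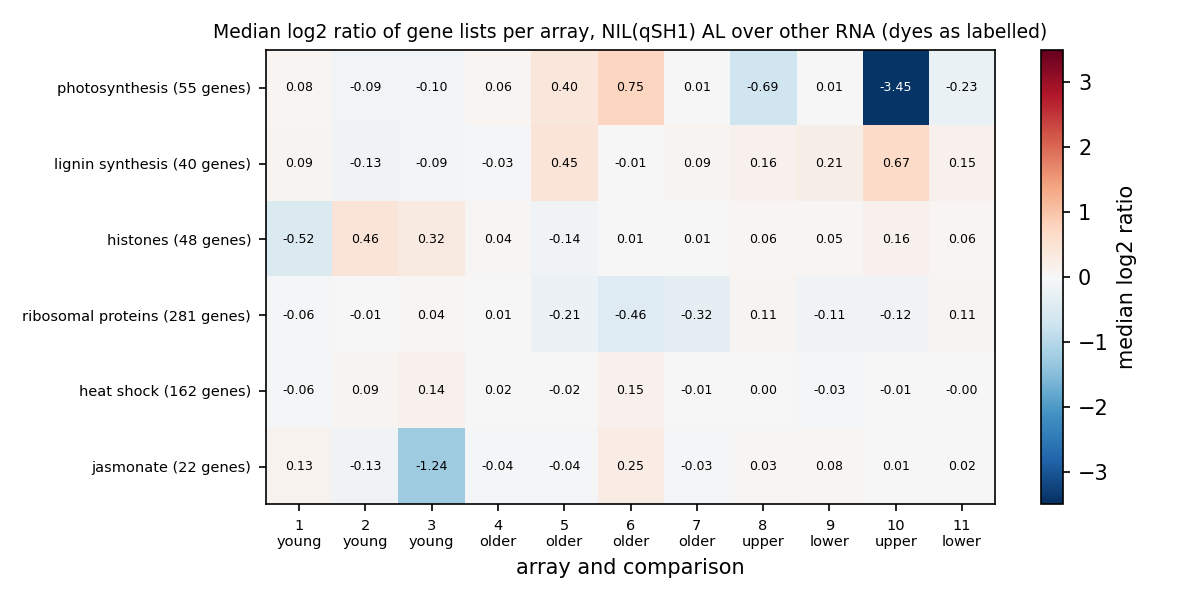
Median log2 ratio of 6 of the 31 gene lists on each of the 11 arrays, dyes as labelled, NIL(qSH1) abscission layer over the other RNA; the lists shown were picked after the values were seen. Photosynthesis genes stood at -3.45 on array 10 and -0.69 on array 8, and histones at -0.52 on array 1 against 0.46 and 0.32 on arrays 2 and 3.

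The region comparisons asked what sets the abscission layer apart from its neighbours in NIL(qSH1). Against the upper region, 4 probes were higher and 24 lower in the layer, 28 probes of 19 genes, with 2747 at an unadjusted p under 0.05. The transcription factor genes Os01g0702700 (MYB1) and Os07g0505200 (squamosa promoter binding protein-like 5) fell by 2.17 (SE 0.28, adjusted p = 0.0368) and 1.97 (SE 0.28, adjusted p = 0.0461). The cyclin-dependent kinase inhibitor gene Os09g0459900 fell by 1.59 (SE 0.22), the protein kinase gene Os03g0241600 by 1.49 (SE 0.20) and homocysteine S-methyltransferase gene Os12g0607000 by 1.41 (SE 0.18), all at adjusted p = 0.0368 and below 0 in 2 of 2 arrays, though a second probe of Os12g0607000 stood at -0.59 and did not pass. Higher in the layer were 2 probes of the methionine synthase gene Os12g0623900, at 1.85 (SE 0.25) and 1.77 (SE 0.22), 1 probe of its neighbour Os12g0624000 at 1.62 (SE 0.22), and Os04g0332700, a conserved hypothetical protein, at 1.93 (SE 0.20). The brightest probes of the 2 methionine synthase genes, at 1.98 (adjusted p = 0.0703) and 1.81 (adjusted p = 0.0576), did not pass, nor did another probe of Os12g0623900 at 1.94. The 4 probes that passed were named after their values were seen, and the 2 methionine synthase genes share a description, so their probes may not tell them apart.

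Photosynthesis genes had a median of -2.14 against the upper region, or -4.29 with the log ratios of Feature Extraction. Of 55 measured members 1 was lower over all genes tested and 41 when adjusted over the list alone. The photosystem II 10 kDa gene Os07g0147500 passed at adjusted p = 0.0368 and was at least 2.32-fold lower in the layer, where it was not well above background. Chlorophyll a/b binding protein gene Os01g0600900, part of the light-harvesting antenna, had a ratio of -4.85 (SE 0.72, adjusted p = 0.0576). The list median was -0.69 on array 8 and -3.45 on array 10, and the camera call at adjusted p = 1.23e-42 was lost with an estimated correlation (adjusted p = 0.469). Array 8 was dim and came from panicles of 50 to 100 mm, array 10 from panicles of 140 mm. Dimness, slide and panicle length cannot be told apart between these arrays. Of 40 lignin synthesis genes 9 were higher and 1 lower over the list alone and 0 passed over all genes tested, with a median of 0.34. That median was 0.16 on array 8 and 0.67 on array 10, and it became 1.38 with the log ratios of Feature Extraction and 0.62 with an offset of 10. The smallest p values among the 9, named after their values were seen, belonged to 4-coumarate-CoA ligase Os02g0177600 at 1.71 (SE 0.32), cinnamyl-alcohol dehydrogenase Os02g0187800, which makes the lignin monomers, at 1.69 (SE 0.36) and caffeoyl-CoA O-methyltransferase Os08g0498100 at 2.14 (SE 0.47). The largest ratio among them was that of phenylalanine ammonia-lyase Os02g0627100 at 2.83 (SE 0.74). A second probe of that last gene, not well above background in the upper region, gave 0.42. The camera adjusted p of 1.20e-09 became adjusted p = 0.469 with an estimated correlation. The YABBY gene Os03g0650000 at -1.57 (SE 0.40, adjusted p = 0.159) and JUBEL2 at -0.89 (SE 0.18, adjusted p = 0.0919) did not pass. OSH15 stood at 1.62 (SE 0.26, adjusted p = 0.0576). Leaving out array 10 ended all 28 calls, leaving out array 8, which was dim, gave 885, and turning array 1, which enters only through the pooled spread, gave 229, with 53 higher and 176 lower. In that last fit OSH15 passed at adjusted p = 0.0334 and 9 photosynthesis genes were lower over all genes tested. The call count also moved without other arrays, to 42 without array 1, 45 without array 5, 8 without array 7 and 6 without array 9 or array 11, to 3 without array 3 and to 1 without array 2 or array 4. It was 0 with a gene-specific dye term, 0 with only the 2 arrays of this comparison, 1 under median centring and 5 with arrays 1 and 2 averaged. It was 908 (124 higher, 784 lower) with the log ratios of Feature Extraction, 692 (113 higher, 579 lower) with an offset of 10, 316 (54 higher, 262 lower) with arrays scaled to each other, 308 (74 higher, 234 lower) with array weights and 89 (38 higher, 51 lower) with a stricter filter on dim probes.

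Against the lower region limma called 0 probes, with 875 at an unadjusted p under 0.05 and a smallest adjusted p of 0.114 (0.0614 with array 1 turned). OSH15 had the largest ratio among the shattering genes, 2.12 (SE 0.26, adjusted p = 0.114, above 0 in 2 of 2), followed by cinnamyl-alcohol dehydrogenase Os02g0187800 at 0.76 (SE 0.36) and Os04g0649100 at 0.70 (SE 0.24). A second probe of Os04g0649100, not well above background in the lower region, gave 0.11. The F-box gene Os02g0757700 stood at 1.43 (SE 0.18, adjusted p = 0.114) and the arginine/serine-rich protein gene Os05g0105900 at 1.56 (SE 0.21, adjusted p = 0.177). Cytoplasmic phosphoglucomutase Os03g0712700, an enzyme of sugar metabolism, stood at -0.73 (SE 0.09, adjusted p = 0.114), with -0.62 to -0.07 at its 5 other probes, and actin-depolymerizing factor 2 gene Os05g0113400 at -1.20 (SE 0.23, adjusted p = 0.427). The shattering list had a median of 0.55, 1 member higher over the list alone and a camera adjusted p of 7.27e-05, which became adjusted p = 0.110 with an estimated correlation. The list median was 1.22 with the log ratios of Feature Extraction, 0.84 with an offset of 10 and 0.29 under median centring, where the camera call was lost. With array weights limma called 45 probes (31 higher, 14 lower), with the log ratios of Feature Extraction 5 higher, and without array 8, without array 10 or with only the 2 arrays of this comparison 1.

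Averaged over both flanking regions, 3 genes were higher in the layer and 0 lower, with 2181 probes at an unadjusted p under 0.05. OSH15 rose by 1.87 (SE 0.18), Os02g0757700 by 1.24 (SE 0.13) and Os05g0178300 by 0.76 (SE 0.08), all at adjusted p = 0.0268 and above 0 in 4 of 4 arrays. With dyes as labelled each passed with 1 probe, and their other probes did not, at 1.40, 1.43 and 1.64 for OSH15 (Os07g0129700), 1.12 for Os02g0757700 and 0.74 for Os05g0178300. The qSH1 locus stood at 0.44 (SE 0.34, adjusted p = 1.00). Of 48 histone genes 0 passed over all genes tested and 6 were higher over the list alone, with the smallest p for the histone H3.3 gene Os03g0390600 at 0.67 (SE 0.11), named after its value was seen, with a camera adjusted p of 6.29e-06 and adjusted p = 0.644 with an estimated correlation. Lignin synthesis genes had a median of 0.20, or 0.49 with the log ratios of Feature Extraction and 0.31 with an offset of 10, with 9 of 40 higher and 1 lower over the list alone and adjusted p = 0.400 with an estimated correlation, and phenylalanine ammonia-lyase Os02g0627100 at 2.89 (SE 0.52, adjusted p = 0.142), named after its value was seen, was among them, though its second probe gave 0.34. Photosynthesis genes had a median of -1.16, or -2.31 with those log ratios, with 37 of 55 lower over the list alone, 0 over all genes tested and adjusted p = 0.400 with an estimated correlation. The 3 to 0 split of calls was 97 higher to 262 lower with the log ratios of Feature Extraction, 74 to 128 with a background offset of 10, 12 to 15 with arrays scaled to each other, 100 to 72 with array weights and 14 to 4 with a stricter filter on dim probes. Of the 3 probes, 0 were among the calls with arrays scaled to each other. Among the calls with the log ratios of Feature Extraction and with the stricter filter were 2, and 3 with that offset and with array weights. Turning array 1 gave 25 higher and 14 lower, among them AUX/IAA gene Os03g0742900 at 1.81 (SE 0.26) and ethylene response factor 2 gene Os09g0434500 at -1.22 (SE 0.17). The 3 calls became 590 without array 8, 19 without array 5, 5 without array 6, 1 without array 7 or array 10, and 0 without array 1, 2, 3, 4, 9 or 11. With a gene-specific dye term 1 probe was called, which was none of these 3. With only the 4 region arrays, with arrays 1 and 2 averaged or under median centring 0 were called.

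Between the flanking regions themselves, 2 probes were higher in the upper than in the lower region and 0 lower, with 1655 at an unadjusted p under 0.05. The DnaJ-family chaperone gene Os04g0549600 was higher by 1.64 (SE 0.17, adjusted p = 0.0482), with 1.37 and no call at its second probe. A probe of acid phosphatase gene Os01g0191200, named after its value was seen, passed at adjusted p = 0.0482, but no probe of that gene was well above background in the lower region on either array, so its size is not given, and its 5 other probes did not pass. Both calls were lost when arrays were paired by panicle stage, a fit that called 1 probe and shared 0 with these 2, and with slide as a random block, which called 0. Photosynthesis genes had a median of 1.96 toward the upper region, or 3.95 with the log ratios of Feature Extraction, with 22 of 55 higher over the list alone, 0 over all genes tested and adjusted p = 0.791 with an estimated correlation. Within 1 slide arrays 8 and 9 had list medians of -0.69 and 0.01, and within another arrays 10 and 11 had -3.45 and -0.23. With array 1 turned the count stayed at 2, while it was 27 with the log ratios of Feature Extraction, 10 with array weights, 4 with arrays scaled to each other and 0 with an offset of 10, a gene-specific dye term, arrays 1 and 2 averaged or only the 4 region arrays. Leaving out any array other than array 8 gave 0, and leaving out array 8 gave 468.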

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

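The tests in this part were chosen after the results were seen, except the test of compressed ratios on array 7, the splits of arrays by stage and the sign patterns of the 4 region arrays. The variety difference of the carbohydrate kinase gene Os01g0105900 stood above 0 on all 3 young arrays and below 0 on all 4 older arrays, with dyes as labelled, a difference of -1.06 (SE 0.18, adjusted p = 0.566). The F-box gene Os04g0385600 did the same, with a difference of -0.95 (SE 0.23, adjusted p = 0.748). Turning array 1 left 2 of 3 young arrays above 0 for each, and the differences were -0.98 (SE 0.20, adjusted p = 0.0526) and -0.94 (SE 0.23, adjusted p = 0.0813). Both drew notice for these opposite directions, and limma's test of the difference passed for neither in either direction of array 1. Of 18 genes tested for an array far from the others, 0 had one.

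Array 1 correlated at -0.75 with array 2 although both carry the same dyes as labelled. Dye bias of single genes would make such arrays alike, so the correlation of -0.746 argues against it. The largest correlation of array 1 with others of its slide was 0.120 in size. Those arrays, 7 to 9, are dim and have the other dye order, and arrays 2 and 3 have a slide of their own. A low correlation therefore cannot decide on a slide effect, which stays open. Exchanged dyes remain open too. Over 93 genes at and near qSH1, array 1 correlated at -0.23 with the mean of arrays 4 to 7, the 13.2 percentile of 1000 random sets. Arrays 2 and 3 lay at 90.2 and 91.7, and the value of array 1 falls between the bounds set for either reading. The 93 include the qSH1 locus itself, at -0.30, 0.65 and 0.42 on arrays 1, 2 and 3 and high on arrays 4 to 6. It could move these correlations, which were not computed without it. A biological difference between young panicles of these arrays was not tested.

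Over all 162 heat shock genes the medians were 0.09 and 0.14 on young arrays 2 and 3 and 0.15 on older array 6, while 21 members picked for their call in the young stage with array 1 turned stood at 1.74, 1.78 and 0.98 there. In a fit of all genes without array 1 and the dim array 7, limma called 6 of the 162 lower in the older stage and 0 higher, which argues against a fixed variety difference as the whole cause for those 6, all among the 21. For the other 15 members it cannot be told apart, since they were picked by their young values and were not called lower. Arrays 2 and 3 are a slide of their own in that fit, so slide and stage cannot be told apart there. By the labels panicle lengths were equal on array 2 (8 mm in both RNAs) and unequal on array 3 (10 and 7 mm). Unequal panicle lengths stay open as a part of the pattern on array 3. The ratio of array 2 to array 3 over the 162 was 0.644 (bootstrap interval over members 0.264 to 0.964), which crosses the bounds set. Handling at harvest was not tested and stays open, as does a biological difference between stages.

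The qSH1 locus was high on older arrays 4 to 6 and not on array 7. Arrays 4 to 6 share a slide that holds no other array, so an effect of that slide cannot be told apart. Dye bias as the whole cause is argued against, because the lowest of arrays 4 to 6 exceeded the highest of arrays 1 to 3, which share their dyes, by 1.24 (SD of arrays 4 to 6 0.338), though array 7 has the other dye and slide, so part of the gap could be dye bias. A poorly matching single probe is argued against by 2 of 3 probes with a mean over 1. Over 72 probes with large ratios on arrays 4 to 6, array 7 kept 0.169 of the ratio (0.116 to 0.347), an interval that crosses the bound set beforehand. For the qSH1 locus that share was 0.0707, the 31.9 percentile of the 72. The 72 were picked by their ratios on arrays 4 to 6, which share a slide and dye order. A smaller ratio on array 7 could follow from that choice, from slide or from dye. Compression on this dim array therefore cannot be told apart from these or from a lower ratio there.

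For the variety comparison as labelled, 19 of 64 sign patterns of the 7 arrays called at least the 1 probe of the real pattern, and chance is not excluded. The highest other pattern, 992 probes, is that with array 1 turned, which points to a structure of the arrays. With array 1 turned, 1 of 64 patterns reached 992 and the highest other called 375, but its sign was turned because of these same values, so this excludes nothing. The stage comparison as labelled called 0 probes, which 35 of 35 splits reach by construction, so this says nothing of chance. The split that sets arrays 2, 3 and 6 apart called 125, which points to a structure of the arrays. With array 1 turned, 1 of 35 splits reached 327 and the highest other called 68, a share that met the criterion written beforehand but is not read as excluding chance, for the same reason. For both flanking regions 1 of 8 sign patterns reached 3, the highest other called 2, and 8 patterns are too few for a share under 0.05.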

How the results depend on the processing

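Counts of probes are given in the order variety, stage, upper region, lower region, both flanking regions, upper against lower region, and were 1, 0, 28, 0, 3 and 2 as reported. The alternatives that turn arrays were chosen after seeing the data, and the cause of a change was not tested unless stated. Keeping flagged spots, dropping the filter, or a random block for alike labels (consensus correlation 0.0808) moved no count by over 1.5 times.

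With the Feature Extraction log ratio, and with the series value table, which holds the same values, the counts were 19, 0, 908, 5, 359 and 27. Median centring without loess gave 15902 (14375 higher, 1527 lower), 0, 1, 0, 0 and 0, and it shifted the median of all probes. An offset of 10 gave 7, 0, 692, 0, 202 and 0, and scale normalization between arrays 5, 0, 316, 0, 27 and 4. The strict filter on dim probes, with 9791 probes, gave 1, 0, 89, 0, 18 and 0. A gene-specific dye term gave 46, 2, 0, 0, 1 and 0. That term rests on the dim array 7 against arrays 4 to 6, the only arrays of 1 kind with both dye orders. With 1 variety coefficient the counts were 0 for variety, 42, 0, 0 and 1 for the others. Arrays 1 and 2 averaged gave 1, 0, 5, 0, 0 and 0. Slide as a random block (correlation -0.0173) gave 3, 0, 28, 0, 3 and 0. Array weights gave 2, 0, 308, 45, 172 and 10. An intensity trend and robust prior gave 0 in all 6, with 2962, 1799, 2659, 708, 2021 and 1596 probes at an unadjusted p under 0.05 in limma. With 1 probe per gene the counts were 2, 0, 14, 0, 3 and 0, and with only the comparison's arrays 1, 1, 0, 1, 0 and 0. Pairing upper and lower arrays by panicle stage, as a replicate block, gave 1 for upper against lower, which was neither of the 2 reported.

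The sign of array 1 turned gave 992, 327 (127 higher, 200 lower), 229, 0, 39 and 2, and turned and averaged with array 2 it gave 15, 88 (21 higher, 67 lower), 41, 0, 0 and 0. The signs of arrays 2 and 3 turned gave 52, 1302 (791 higher, 511 lower), 229, 0, 39 and 2. Leaving out each array in turn gave 0 to 445 for variety, 0 to 310 for stage, 0 to 885 for the upper region, 0 to 1 for the lower region, 0 to 590 for both flanking regions and 0 to 468 for upper against lower. Where this leaves a region with 1 array, that array is assumed to vary like the others. Of the 28 upper-region probes 27 were also called with the Feature Extraction log ratio, 28 with an offset of 10 and 28 with array 1 turned. With 1 variety coefficient 21 of them were called and with the strict filter 14. With the dye term, under median centring and with only the comparison's arrays 0 of them were called. The tally of named genes leaves out the turn of arrays 2 and 3 and the young stage. Within that tally no direction of a named gene that passed was reversed: of named genes under alternatives 2300 values stayed on their side of the threshold, 265 lost it, 77 gained it and 138 that passed in neither moved by more than the spread between arrays. Passing genes named for their size had 1 direction on all arrays by the naming rule. A reversal was therefore unlikely from the start, and its absence says little of stability. The tally of gene lists leaves out the same and covers only the changed scalings, the dye term, the estimated correlation and array 1 turned. Of gene lists called by camera 172 values stayed, 51 lost the call and 8 medians changed sign, all under median centring, which moved the median of all genes to 0.37 over 7 arrays, 0.15 for stage and 0.45 in the older arrays. Over 7 arrays these medians became 0.52 for gibberellin, 0.46 for jasmonate, 0.22 for abscisic acid, 0.83 for ribosomal protein and 0.12 for defence genes, in the stage comparison 0.065 for ribosomal protein genes, and in the older arrays 0.25 for abscisic acid and 0.86 for ribosomal protein genes. Both abscisic acid medians, that of defence genes and that of ribosomal protein genes by stage stayed below the median of all genes, so relative to it they kept their direction, and the others did not. The cause was not tested. Signal over background limits arrays 7 to 9, where 14.0% to 14.7% of probes in the layer channel were well above it.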

Other observations

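Genes in this part were chosen after their values were seen, and no test beyond limma's was run on them. Against the upper region the floral homeotic MADS-box gene Os06g0712700 (SPW1) had a ratio of 1.97 (SE 0.41, adjusted p = 0.0949), the only 1 of 24 MADS-box genes past the threshold when adjusted over the list alone. Of 5 YABBY genes 2 were lower over the list alone, Os03g0650000 and Os12g0621100 (FIL, adjusted p = 0.184). Of 20 cellulose synthesis genes 2 were lower, with the smaller p for Os10g0341700 at -1.11 (SE 0.20, adjusted p = 0.0659) with -0.82 to -0.63 at its 4 other probes, and 2 were higher, with the smaller p for Os09g0422500 (adjusted p = 0.234). Of 14 pollen and anther genes, a marker of flower tissue, 2 were lower, Os10g0371000 at -1.57 (SE 0.25, adjusted p = 0.0576) and Os11g0167800 (adjusted p = 0.0738). No size is given for Os12g0621100, Os09g0422500 and Os11g0167800, because the probe used was not well above background in 1 of the 2 RNAs on both arrays. Over all genes tested 0 members of these 4 lists passed by limma.

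Of 281 ribosomal proteins 2 were higher and 13 lower against the upper region over the list alone, and the median of the list was -0.00021. Of the 13 lower ones 9 are described as 50S, 30S or chloroplast proteins, which belong to organelle ribosomes, and photosynthesis genes had a median of -2.14 in the same comparison. Among the 9 were Os02g0137200 (50S protein L3-1) at -1.83 (SE 0.29, adjusted p = 0.0576) and Os02g0259600 (50S protein L21) at -1.60 (SE 0.31, adjusted p = 0.0753), which did not pass over all genes tested.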
